A study of Homo sapiens with 24 samples.

How the data were processed

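The series measured messenger RNA by catabolic SLAM-seq in 24 libraries from 2 lines of HEK293, an established human embryonic kidney line that is easily transfected and widely used for expression studies. SLAM-seq adds 4-thiouridine (s4U) to living cells, which build it into new RNA; alkylation of the extracted RNA then makes s4U read as C, so that T>C conversions mark RNA made during the pulse. Per the labels' protocols, cells received 100 µM s4U with 1 µg/mL doxycycline for 24 h, were washed, and were then given 10 mM uridine as a chase. RNA was taken at 0, 2, 4 and 6 h of chase from a control line carrying a Flag/HA construct and from a line overexpressing ZC3H7B (ZC3H7B-OE), with 3 libraries per line and time, hence 8 groups. Libraries were poly(A)-selected, prepared with a directional kit and sequenced as paired ends, per the labels.

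The authors deposited 2 tables of counts for the whole series, one of all reads and one of reads with T>C conversions, called labelled reads here. Both hold whole-number read counts per gene, not normalized, over 19692 entries, of which 19242 name 1 gene and 450 name several genes that share a region. The submitters' processing notes name fastp, with no version, and the genome build GRCh37. The aligner, the caller of conversions, the number of conversions a labelled read needs and the counting rule are not given in the sources used here. Of genes with an annotated 3' UTR, 94.5% are in the tables, against 18.4% of genes without one. Labelled reads never exceeded all reads of an entry. Entries naming several genes held between 2.30% and 3.69% of a library's reads and stayed in library sizes and tests. Whether the counting used strand is not given either, so genes that overlap an antisense neighbour or share reads with a close copy are uncertain. Gene symbols are those of the tables.

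Depth ran from 1502070 to 3676250 reads per library, and from 830574 to 1579740 labelled reads. At this depth a list gene with a few reads per library cannot be compared, and 16669 of the entries had at least 1 read in any library. PCR reads without molecular identifiers are not independent molecules, so intervals given here (exact 95% intervals of counts and shares) and the floor of 3 counts used for a group at 0 cover counting error only. The labels call the libraries replicates but do not say that they came from separate cultures, so p-values measure only the spread between these samples, which may be technical. No pair of replicates was a duplicate: a chi-square comparison of read counts gave between 2.32 and 34.8 per degree of freedom.

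All reads were tested with edgeR 4.0.16 in R 4.3.3: quasi-likelihood fits with robust estimation on all 24 libraries, a mean per group, TMM scaling and edgeR's filterByExpr (minimum count 10), which kept 10038 entries. Contrasts compared ZC3H7B-OE with control as the mean of the 4 times and at each time, tested whether that difference changed along the chase (an F test of the interaction), and compared 6 h with 0 h in control. Fold changes are fitted log2 values with standard errors (SE), and p-values carry a Benjamini-Hochberg adjustment with a threshold of 0.05. Levels are given as CPM scaled by TMM. Labelled reads were fitted with the library sizes and TMM factors of all reads, on 8763 entries, with a slope over hours in each line. A half-life is 1 h divided by the size of a negative slope in log2 units per h. It describes the fall of labelled reads relative to all reads, which includes dilution by new mRNA and by growth. A single slope spans 0 to 6 h, although the labelled share of a library's reads changed little until 2 h. The fall was thus not log-linear, and a half-life averages over this lag. The share of labelled reads per library was compared by a two-sided exact permutation test.

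Before the data were examined, the groups, these tests, most of the alternatives tried, the gene lists and the rule for naming genes were fixed. The rule names ZC3H7B and ZC3H7A; the 10 highest and 10 lowest called genes with a mean log2 CPM of at least 1 and the same sign at all 4 times; the 5 steepest and 5 shallowest called losses in control with at least 50 labelled reads at 0 h; the 5 highest and 5 lowest called changes between 0 and 6 h; and up to 4 members with the smallest adjusted p from each list that passed its test and from the lists of mRNA decay, deadenylation and the microRNA pathway. The rule offered the same for differences in loss rate, where 0 genes were eligible; it chose from 3668 genes for all reads, 3533 for falling labelled reads in control and 5834 for the chase. The lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01 where at least 5 members were tested, with an estimated correlation and with fry beside it; camera's direction is relative to other genes, while fry asks whether a list's own genes move one way and does not compare them with other genes. Counts of list members past the gene test are given over all genes tested and, where they differ, adjusted over the list alone.

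The lists covered CCR4-NOT and deadenylation; decapping, translational repression and ribosome quality control; the exosome and SKI complex; the microRNA pathway; translation factors; cytosolic aminoacyl-tRNA synthetases; cytosolic and mitochondrial ribosomal proteins; C2H2 zinc finger genes named ZNF; replication-dependent histones; mitochondrially encoded mRNAs; the nuclear-encoded respiratory chain; cholesterol synthesis; the integrated stress response; endoplasmic reticulum chaperones; p53 targets; heat shock and cytosolic chaperones; immediate early and other short-lived mRNAs; long-lived glycolytic and housekeeping mRNAs; hypoxia targets; S phase; mitosis; the interferon response; NF-kB targets; nucleotide salvage; ribosome biogenesis; extracellular matrix; neuronal genes; and markers of fibroblasts, leukocytes and epithelia, cell types other than HEK293. Mitochondrially encoded mRNAs had 0 entries in the tables.

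Codon composition was taken from GENCODE release 29 on GRCh38, matched by gene identifier only (18071 single-gene entries, 93.9%), with no coordinates used. GC3, the share of codons whose last base is G or C, was computed on the longest coding sequence of each gene and set against fold changes by Spearman's rho across genes, with camera tests of the fifth of genes with the lowest and the fifth with the highest GC3. Genes in such correlations are not independent replicates. Each of the 61 sense codons was treated likewise.

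Alternatives were DESeq2 1.42.0 (size factors in the edgeR fit, and its Wald or likelihood ratio test), limma-trend with a prior count of 2, no filter, a stricter filter (mean count of at least 50), the replicate number as a block, only the 6 libraries of a contrast, each library or time left out, a minimum of 1.5-fold, ZC3H7B removed, and for labelled reads TMM on those reads themselves, an offset of each gene's own total and other sets of times. Some comparisons were added after the results were seen: 6 h against 0 h in ZC3H7B-OE, 2 h against 0 h in control, the lists on the chase, and labelled against unlabelled reads of the same gene, fitted with a library term for both kinds of read so that a gene's own total cancels.

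The comparisons named here were tested on simulated counts with the real library sizes; the interaction, changes along the chase, slopes within a line and fry were not simulated. For the mean of the 4 times, 60% of planted 1.5-fold and 91.8% of planted 2-fold changes among 9776 tested genes were recovered, with 9 false calls. For the difference in loss rate, 0% of planted changes of 0.1 and 8.25% of 0.2 log2 per h were recovered among 8555 genes, with 2 false calls, so this comparison has little power for single genes. Labelled against unlabelled reads at 6 h recovered 31% and 70.1% of planted 1.5-fold and 2-fold changes among 8763 genes, with 8 false calls. The offset of each gene's own total gave 89 false calls among 8620 genes and is used as an alternative only. Camera found a planted list and called 0 of 200 random lists. Random lists are not made of genes that vary together, so this check cannot show how often camera at the preset correlation wrongly calls correlated lists. In the real lists, for the line difference in all reads, estimated correlations ran from -0.0407 for nucleotide salvage to 0.459 for cytosolic ribosomal proteins. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.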

Results

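Poly(A) RNA was measured in 2 HEK293 lines, a control line with a Flag/HA construct and a line overexpressing ZC3H7B, a CCCH-type zinc finger protein. Both were labelled with 4-thiouridine for 24 h under doxycycline and collected at 0, 2, 4 and 6 h of a uridine chase, with 3 libraries in each of 8 groups. The series concerns how ZC3H7A and ZC3H7B act on translation and mRNA stability through codons, so mRNA levels, loss of label and their relation to codon use were compared between the lines. Libraries held 1502070 to 3676250 reads, of which 830574 to 1579740 were labelled, that is, carried T>C conversions.

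Labelling was high at the end of the pulse and fell late in the chase. In control, labelled reads made up 76.7% ± 1.67 (SD, n = 3) of all reads at 0 h, 75.7% ± 1.82 at 2 h, 47.7% ± 0.759 at 4 h and 29.9% ± 0.729 at 6 h. In ZC3H7B-OE the share was 74.8% ± 0.420, 71.8% ± 0.860, 45.5% ± 0.521 and 29.6% ± 0.660. ZC3H7B-OE minus control was -1.95, -3.93, -2.18 and -0.289 percentage points at the 4 times. At 6 h this ran from -0.692 without control replicate 2 to 0.0592 without ZC3H7B-OE replicate 1, so its direction rested on a single library. Two-sided exact permutation tests gave p = 0.3, 0.1, 0.1 and 0.6 (adjusted 0.4, 0.2, 0.2 and 0.6), and 0.1 is the smallest p that 3 against 3 libraries allow. Control 0 h replicate 3 stood apart from the other libraries. It had 11032 genes with a read (others 12005 to 13201), 10.7% of its reads in 10 genes (others 3.56% to 7.61%), a TMM factor of 0.724 and a mean correlation of 0.912 with its group (others 0.939 to 0.98).

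**Figure D1:**
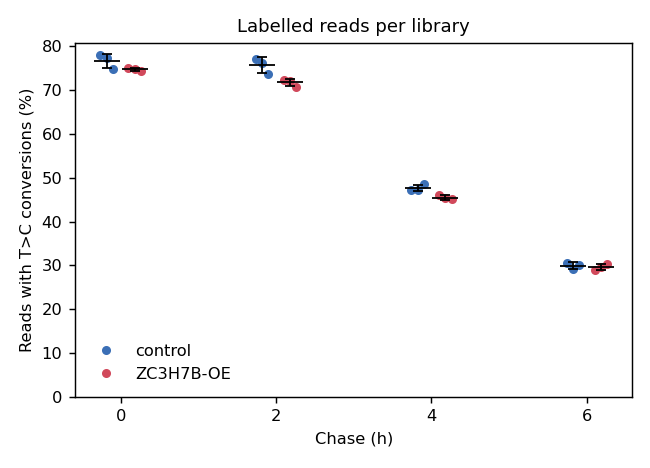
Share of reads with T>C conversions (%) against hours of chase, with a point per library and black bars for the mean ± SD of 3 libraries of each line. The share stayed near its starting value until 2 h and fell to 29.9% in control and 29.6% in ZC3H7B-OE by 6 h.

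ZC3H7B itself was higher in ZC3H7B-OE, by a log2 fold change of 0.28 (SE 0.08, edgeR adjusted p = 0.0035, 12 libraries per line). Its mean level was 329 ± 75.3 TMM-scaled CPM (SD, n = 12) against 270 ± 74.2 in control, from 9173 and 7362 reads, a 1.22-fold difference. In control the replicates held 348, 359 and 193 CPM at 0 h, 376, 377 and 283 at 2 h, 205, 220 and 249 at 4 h, and 203, 221 and 209 at 6 h. In ZC3H7B-OE they held 454, 465 and 412 CPM at 0 h, 291, 358 and 325 at 2 h, 285, 275 and 295 at 4 h, and 262, 255 and 273 at 6 h. By time the log2 difference was 0.55 at 0 h (adjusted p = 0.00699), -0.09 at 2 h (0.805), 0.34 at 4 h (0.127) and 0.32 at 6 h (0.168). With 0 h left out of the mean it was 0.19, and the call was lost (adjusted p = 0.0976, range over the alternatives 0.000427 to 0.0976). Without control 0 h replicate 3, which held 193 CPM, the mean over the times was 0.222, so the difference at 0 h rests in part on that library. Genes without an annotated 3' UTR are largely missing from the tables, so whether reads of a construct lacking the gene's own 3' UTR were counted is not known.

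The labelled share of ZC3H7B reads was lower in ZC3H7B-OE at 6 h of chase. It went from 81.5% ± 8.15 at 0 h to 45.2% ± 0.871 at 6 h in control, and from 63.8% ± 2.03 to 21.5% ± 1.36 in ZC3H7B-OE (SD, n = 3). At 6 h the log2 odds of labelled against unlabelled ZC3H7B reads were -1.59 relative to control (SE 0.24, adjusted p = 0.000632). The slopes of labelled reads were -0.25 (SE 0.04) and -0.40 log2 per h (SE 0.04), half-lives of 4.00 h in control and 2.53 h in ZC3H7B-OE, and their difference of -0.15 (SE 0.05) did not pass the test (adjusted p = 0.811).

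ZC3H7A, the paralog of ZC3H7B, had a log2 difference of -0.20 (SE 0.10, adjusted p = 0.0898), with 58.2 ± 18.4 CPM in control and 53.6 ± 23.0 in ZC3H7B-OE (SD, n = 12). Its control replicates held 35.4, 36.4 and 26.7 CPM at 0 h, 53.7, 45.9 and 61 at 2 h, 69.7, 64.8 and 71.0 at 4 h, and 72.3, 81.3 and 80.1 at 6 h. Those of ZC3H7B-OE held 29.1, 16.5 and 22.0 CPM at 0 h, 51.3, 43.5 and 53.6 at 2 h, 66.8, 90.6 and 84.1 at 4 h, and 56.4, 64.0 and 65.2 at 6 h. At 0 h alone ZC3H7A was lower in ZC3H7B-OE (log2 -0.58, adjusted p = 0.0420). Over all times it passed the test with 4 h left out (-0.34, adjusted p = 0.0157) and without control 0 h replicate 3 (0.0368), control 2 h replicate 2 (0.0484) or ZC3H7B-OE 0 h replicate 1 (0.0328). The half-life of labelled ZC3H7A reads was 4.46 h in control and 4.57 h in ZC3H7B-OE.

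**Figure D2:**
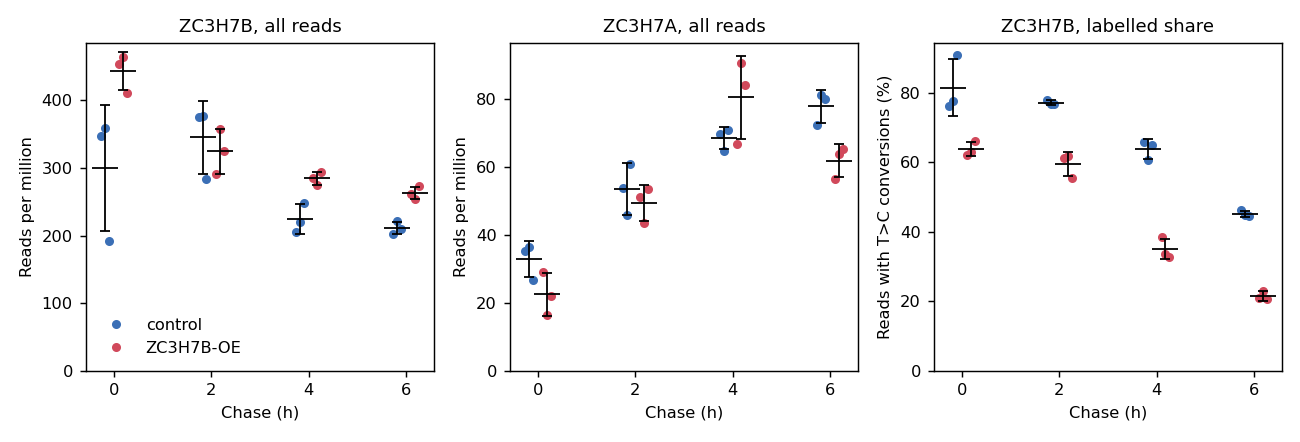
ZC3H7B and ZC3H7A in CPM and the labelled share of ZC3H7B reads (%), against hours of chase, with a point per library and black bars for the mean ± SD of 3 libraries. At 0 h ZC3H7B lay between 412 and 465 in ZC3H7B-OE and between 193 and 359 in control, while its labelled share was lower in ZC3H7B-OE.

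The largest single differences between the lines were mostly of genes with few reads in one of them. No uninduced libraries were analysed here, so a difference between the lines from before induction cannot be told from an effect of ZC3H7B. For comparisons of the lines, here and below, fell and rose mean lower and higher in ZC3H7B-OE than in control. LCP1, the actin-bundling protein L-plastin of leukocytes, was 20.7-fold higher in ZC3H7B-OE (95% counting interval 18.4 to 23.4), with 11.1 CPM in control and 218 in ZC3H7B-OE (log2 4.37, SE 0.13, adjusted p = 6.19e-23). TENM1, a teneurin of the nervous system, fell from 921 reads over the 12 control libraries to 10 in ZC3H7B-OE, a ratio of 94.8 (51.3 to 198). LIPH, a phospholipase, fell by 3.97 on the log2 scale (SE 0.16), CGA, the alpha subunit of glycoprotein hormones, by 3.94 (SE 0.29), and SNAI2, a transcriptional repressor, by 3.91 (SE 0.58). Among the other low genes, ZC3H7B-OE held 9 reads of the zinc finger gene ZNF502 against 496 in control, and 4 of PVRL3, a nectin, against 212. It held 3 reads of ZNF43 against 402 (ratio 138, interval 46.8 to 671), 2 of the metalloproteinase gene MMP16 against 159 (81.8, 22.3 to 681), and 3 of BCHE, butyrylcholinesterase, against 142 (48.7, 16.3 to 239). CHRM3, a muscarinic receptor, had 1 read against 117 (120.4, 21.2 to 4795), and its call was lost without control 0 h replicate 1 (adjusted p = 1).

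Apart from LCP1, the named genes higher in ZC3H7B-OE differed less than those lower in it. ACAD10, an acyl-CoA dehydrogenase family member, rose by a log2 of 2.56 (SE 0.43), AMOT, angiomotin, by 2.25 (SE 0.21), AURKC, an aurora kinase, by 1.94 (SE 0.42), and NAP1L2, a nucleosome assembly protein, by 1.77 (SE 0.46; 2.68 without control 0 h replicate 2). NUP214, a nucleoporin, had a fitted log2 of 2.27 (SE 0.68), DUSP26, a phosphatase, 2.13 (SE 0.44), LEP, the hormone leptin, 1.94 (SE 0.60), PROX2, a homeobox gene, 1.80 (SE 0.63) and C7orf76 1.64 (SE 0.61; 2.67 without control 2 h replicate 3). Control held 0 reads of NUP214, LEP and PROX2 at 0 h and of DUSP26 at 6 h, where the fitted log2 differences were 5.31, 4.48, 4.86 and 5.89 and enter the mean over times. In reads pooled over 12 libraries per line the ratios were 1.60 for NUP214 (84 against 51), 2.25 for DUSP26 (118 and 51), 2.60 for LEP (91 and 34) and 1.69 for PROX2 (528 and 304), all below the fitted 4.81-, 4.37-, 3.83- and 3.47-fold. They were also below the fit for AURKC (2.74 and 3.84), NAP1L2 (2.34 and 3.41), C7orf76 (2.64 and 3.11) and ACAD10 (5.27 and 5.88), and not for AMOT (4.92 and 4.74). Of these calls, NUP214 was lost with 0 h left out (adjusted p = 0.109) or by limma (0.0533) and DUSP26 with 6 h left out (0.0802). LEP was lost without ZC3H7B-OE 0 h replicate 3 (0.117), 0 h (0.0717) or 6 h (0.0672), and PROX2 without control 0 h replicate 3 (0.0539), ZC3H7B-OE 0 h replicate 1 (0.0977), 0 h (0.0794) or 6 h (0.0713). C7orf76 was lost without control 6 h replicate 3 (0.0503), ZC3H7B-OE 0 h replicate 1 (0.0553), 2 h replicate 3 (0.126) or 4 h replicate 2 (0.0515), and without 2 h (0.0556), 4 h (0.0513) or 6 h (0.121).

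In all, 4594 of 10038 tested genes differed between the lines over the 4 times, 2040 higher and 2554 lower in ZC3H7B-OE. Of these, 621 were at least 1.5-fold higher and 1362 at least 1.5-fold lower, and 94 and 451 at least 2-fold. Called genes with the same sign at all 4 times numbered 1684 higher and 2137 lower.

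Stress-response mRNAs were lower in ZC3H7B-OE. Of 26 tested genes of the integrated stress response, which ATF4 drives when translation initiation is limited, 18 fell and 1 rose, also when adjusted over the list alone, with a median log2 of -0.56 (camera adjusted p = 1.28e-06; adjusted p = 0.00403 with an estimated correlation). TRIB3, a pseudokinase, went from 598 ± 73.6 to 251 ± 40.6 CPM (SD, n = 12; log2 -1.25, SE 0.07), the transcription factor ATF3 fell by 1.15 (SE 0.07), DDIT4, an inhibitor of mTORC1, by 0.89 (SE 0.07), and SLC7A1, a transporter of cationic amino acids, by 0.80 (SE 0.07). Of 17 tested p53 targets, 13 fell and 2 rose, also when adjusted over the list alone, with a median of -0.57 (camera adjusted p = 0.000268; adjusted p = 0.0174 with an estimated correlation). CDKN1A, the cell cycle inhibitor p21, fell by 1.20 (SE 0.08), RRM2B, a ribonucleotide reductase subunit, by 1.26 (SE 0.10), CCNG1, cyclin G1, by 1.09 (SE 0.11) and GADD45A by 0.65 (SE 0.08).

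Immediate early mRNAs and chaperones were lower too, but the list tests rested on the preset correlation. Of 37 immediate early and other short-lived mRNAs, 22 fell (23 adjusted over the list alone) and 0 rose, with a median of -0.37 (camera adjusted p = 1.43e-05), but adjusted p = 0.142 with an estimated correlation. EGR1 fell by 1.71 (SE 0.11), KLF10 by 1.04 (SE 0.11) and JUN by 0.55 (SE 0.06); all encode transcription factors. Of 23 heat shock and cytosolic chaperone genes, 13 fell and 0 rose, also when adjusted over the list alone, with a median of -0.32 (camera adjusted p = 0.00313), but adjusted p = 0.685 with an estimated correlation. HSPH1, a chaperone of the HSP110 family, fell by 0.87 (SE 0.07), CHORDC1, which binds HSP90, by 1.11 (SE 0.11), DNAJA1, a J-domain protein, by 0.76 (SE 0.08) and the chaperonin subunit CCT6A by 0.63 (SE 0.07). As many lists passed in 42 of 100 splits of the libraries between the lines, the real one included.

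**Figure D3:**
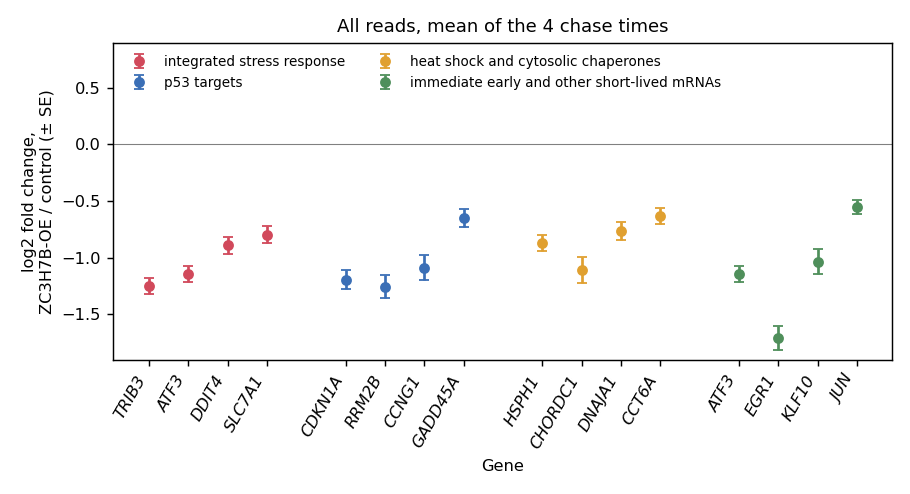
Log2 fold change of all reads between ZC3H7B-OE and control (mean of 4 chase times) for the genes named from the 4 lists that passed the list test, with bars for ± SE. All lie below 0, from -0.55 for JUN to -1.71 for EGR1.

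The machinery of mRNA decay showed changes in single genes and, by camera, none as a list. Fry, which does not compare a list with other genes, called CCR4-NOT and deadenylation lower (adjusted p = 8.65e-05) and the microRNA pathway higher (0.0363), but not decapping (0.208) or the exosome (0.261). Of 15 genes of CCR4-NOT and deadenylation, 8 fell and 3 rose (camera adjusted p = 0.505), among them the deadenylase subunits CNOT6 (log2 -0.41, SE 0.07), CNOT6L (-0.55, SE 0.10) and CNOT7 (-0.44, SE 0.08), and the antiproliferative factor BTG2 (-0.70, SE 0.11). CNOT7 was no longer called with 0 h left out (-0.14, adjusted p = 0.242). Of 25 genes of decapping, translational repression and ribosome quality control, 4 rose and 5 fell (camera adjusted p = 0.505), with the decapping enzyme DCP2 at -1.02 (SE 0.25), its enhancer EDC3 at 0.34 (SE 0.06), and the ubiquitin ligases of stalled ribosomes LTN1 and ZNF598 at 0.38 (SE 0.10) and 0.37 (SE 0.09). Of 12 microRNA pathway genes, 4 rose and 1 fell (camera adjusted p = 0.505): DICER1 rose by 0.59 (SE 0.12), TARBP2 by 0.38 (SE 0.10; adjusted p = 0.105 with 2 h left out) and DGCR8 by 0.27 (SE 0.09; adjusted p = 0.198 with 0 h left out), and PRKRA, a DICER1 partner, fell by 0.93 (SE 0.16). These 3 lists had the same counts adjusted over the list alone.

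Of 13 exosome and SKI complex genes, 2 rose and 2 fell (2 and 1 adjusted over the list alone; camera adjusted p = 0.833). The exoribonuclease DIS3 was at -0.40 (SE 0.07), the helicase SKIV2L at 0.49 (SE 0.14; adjusted p = 0.0704 with 0 h left out) and EXOSC5 at 0.34 (SE 0.10; adjusted p = 0.0963 with 4 h left out). EXOSC8 was at -0.43 (SE 0.18, adjusted p = 0.0490; -0.226 without control 0 h replicate 3). It was lost, with adjusted p from 0.0546 to 0.0882, without control 0 h replicate 3, 2 h replicate 2 or 3, any 4 h replicate, or 6 h replicate 1 or 2, and without ZC3H7B-OE 0 h replicate 2 or 3, any 2 h replicate, 4 h replicate 1 or 3, or 6 h replicate 2 or 3. Leaving out 0 h, 4 h or 6 h lost it as well (adjusted p = 0.313, 0.145 and 0.0768). DESeq2 size factors (0.0583) and limma (0.0661) lost it too.

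The remaining lists did not pass camera (adjusted p of 0.328 or more). Fry called nucleotide salvage and ribosome biogenesis higher (adjusted p of 0.0266 or less). It called tRNA synthetases, histones, cholesterol synthesis, endoplasmic reticulum chaperones, hypoxia targets, S phase, mitosis, extracellular matrix and neuronal genes lower (adjusted p of 0.0106 or less). Among genes of protein synthesis, 6 of 34 translation factors rose and 7 fell (5 and 7 adjusted over the list alone), 3 of 16 aminoacyl-tRNA synthetases rose and 8 fell, 11 of 74 cytosolic ribosomal protein genes rose and 8 fell (9 and 6), 13 of 64 mitochondrial ribosomal protein genes rose and 15 fell (13 and 14), and 6 of 25 ribosome biogenesis genes rose and 6 fell (7 and 6). In metabolism, 12 of 69 respiratory chain genes rose and 13 fell (11 and 9), 4 of 23 cholesterol synthesis genes rose and 9 fell (5 and 9), 9 of 22 glycolytic and housekeeping genes rose and 4 fell (9 and 5), 2 of 16 hypoxia targets rose and 6 fell, and 3 of 10 nucleotide salvage genes rose and 1 fell. In the cell cycle, 6 of 31 S phase genes rose and 10 fell, and 3 of 25 mitosis genes rose and 8 fell. Of 20 histone genes, 7 fell and 0 rose, in poly(A)-selected libraries that would miss histone mRNA without a poly(A) tail. Further, 63 of 329 ZNF genes rose and 67 fell (63 and 66), 3 of 15 endoplasmic reticulum chaperones rose and 5 fell, 5 of 22 extracellular matrix genes rose and 5 fell (5 and 6), 2 of 12 neuronal genes rose and 4 fell, and 0 of 5 interferon response genes changed. Where no second pair is given, the counts adjusted over the list alone were the same. The median and the mean differed in sign for cholesterol synthesis (0.12 and -0.14), extracellular matrix (0.11 and -0.20) and ZNF genes (0.03 and -0.04), and camera's direction differed from both for mitochondrial ribosomal proteins (-0.03 and -0.08).

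Markers of other cell types were too few for a list test, with 0 tested fibroblast, 3 leukocyte and 2 epithelial genes, as were the 4 tested NF-kB targets. EPCAM, an epithelial adhesion protein, was lower in ZC3H7B-OE (-0.47, adjusted p = 0.0147), and the keratin KRT10 had -0.07 (adjusted p = 0.751). The leukocyte genes CD68, FCER1G and CD79A had 0.20, 0.28 and 0.92 (adjusted p = 0.259, 0.394 and 0.107).

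The line difference was present at each chase time. At 0 h, 1170 genes were higher and 1962 lower in ZC3H7B-OE; at 2 h, 220 and 729; at 4 h, 682 and 1090; and at 6 h, 656 and 927. Which time had the most calls depended on the fit: from the 6 libraries of each time alone, 117 were higher and 674 lower at 0 h, 399 and 866 at 2 h, 1452 and 1652 at 4 h, and 1599 and 1687 at 6 h. The total of 3132 at 0 h was 2130 without control 0 h replicate 3. The 949 at 2 h became 585 without control replicate 1 and 575 without ZC3H7B-OE replicate 2. The 1772 at 4 h became 1038 without control replicate 1 and 1150 without ZC3H7B-OE replicate 3. The 1583 at 6 h became 917 and 919 without control replicates 1 and 3, and 990 and 890 without ZC3H7B-OE replicates 2 and 3. The difference itself changed along the chase for 174 genes (edgeR F test of the interaction). It did for 748 by DESeq2's likelihood ratio test and 942 with no filter. This count was 910, 712 and 390 without control 0 h replicates 1, 2 and 3, 108 without control 4 h replicate 1, and 115 and 94 without control 6 h replicates 1 and 3. It was 62, 80 and 48 without ZC3H7B-OE 0 h replicates 1, 2 and 3, and 110 without ZC3H7B-OE 6 h replicate 3.

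Total reads of many genes also changed along the chase within a line, which bears on every measure of loss taken relative to all reads. In control, 3081 of 10038 tested genes were higher and 3004 lower at 6 h than at 0 h, and in ZC3H7B-OE 3295 and 3074. These are changes in reads. Whether mRNA changed or U-rich labelled reads returned after the chase was not settled. At 2 h in control 1346 were already higher and 1101 lower (439 and 150 from the 6 libraries alone). The changes from 0 to 2 h correlated across genes with the U content of the 3' UTR (rho 0.131 in control and 0.490 in ZC3H7B-OE). ZC3H7A rose in control by 1.22 (log2, SE 0.19, adjusted p = 2e-06) and ZC3H7B fell by 0.52 (adjusted p = 0.00536). Deadenylation and decapping genes rose: 11 of 15 CCR4-NOT genes rose and 0 fell (median log2 1.22, camera adjusted p = 1.66e-05; adjusted p = 0.00519 with an estimated correlation), with CNOT6 up by 2.35 (SE 0.14) and CNOT6L by 3.04 (SE 0.21). Of the decapping and quality control genes, 18 of 25 rose and 3 fell (1.71, camera adjusted p = 4.55e-05; adjusted p = 0.0469 with an estimated correlation), with LTN1 up by 3.54 (SE 0.21). Replication-dependent histone genes, measured only as poly(A)-selected RNA, fell, 13 of 20 with 0 rising (-1.50, camera adjusted p = 0.00634, and adjusted p = 0.0469 with an estimated correlation). Histone mRNA without a poly(A) tail would be missed. For these 3 lists the counts adjusted over the list alone were the same.

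A further 6 lists passed in the chase only at the preset correlation. Of the immediate early mRNAs, 28 of 37 rose and 3 fell (29 and 3 adjusted over the list alone; median 1.21, camera adjusted p = 4.69e-06; adjusted p = 0.0688 with an estimated correlation), with KLF10 up by 1.18 (SE 0.22). Among cytosolic ribosomal proteins 58 of 74 fell and 2 rose (-1.61, camera 1.05e-07; adjusted p = 0.454 with an estimated correlation). Among mitochondrial ones 48 of 64 fell and 2 rose (48 and 3 adjusted over the list alone; -1.30, 3.11e-08; adjusted p = 0.374 with an estimated correlation). Of respiratory chain genes 54 of 69 fell and 2 rose (54 and 3 adjusted over the list alone; -1.60, 3.11e-08; adjusted p = 0.374 with an estimated correlation), including NDUFA4, which fell by 2.64 (SE 0.52). Of glycolytic and housekeeping genes 19 of 22 fell and 2 rose (20 and 2 adjusted over the list alone; -1.47, 1.07e-07; adjusted p = 0.236 with an estimated correlation), including GAPDH, which fell by 1.32 (SE 0.16). Of the integrated stress response 12 of 26 fell and 4 rose (-0.43, 0.0497; adjusted p = 0.2 with an estimated correlation), including CHAC1, which fell by 3.66 (SE 0.21). The other 17 lists had camera adjusted p of 0.0997 or more, and fry called 20 of 26. In 4 of 10 splits of the 0 and 6 h libraries, the real one included, at least as many lists passed as the 9 given here.

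The largest rises in control from 0 to 6 h were of genes with 0 reads over the 3 libraries at 0 h. Against a floor of 3 counts over the group, PROX2 was at least 18.1-fold higher (102 reads at 6 h), ZNF326 at least 16.9-fold (95), RALGAPB at least 13.5-fold (76), GPR75 at least 11.7-fold (66) and BOLL at least 8.18-fold (46). BOLL was no longer called without control 0 h replicate 1 (adjusted p = 0.0509) or control 6 h replicate 2 (0.0636). Conversely, DUSP26 had 19 reads at 0 h and 0 at 6 h, at least 11.9-fold lower. PRODH, proline dehydrogenase, had 18 and 1 (ratio 33.7, interval 5.33 to 1406), KIAA0513 15 and 1 (28.1, 4.33 to 1184), C11orf30 33 and 3 (20.6, 6.47 to 105.1) and DGKE, a diacylglycerol kinase, 21 and 2 (19.7, 4.81 to 173).

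Labelled reads were lost fastest from CHAC1, ID3, CDKN1B, FOXB1 and ZNF627. In control, CHAC1, which degrades glutathione, had a half-life of 0.968 h, and its labelled share fell from 94.3% ± 1.86 to 21.5% ± 2.67 (SD, n = 3) over 6 h. Total reads of CHAC1 fell over this time as well, as given above, and that fall enters its half-life. ID3, an inhibitor of DNA binding, had 1.01 h (share 86.4% to 6.79%), CDKN1B, the cell cycle inhibitor p27, 1.01 h (74.6% to 2.26%), FOXB1 1.10 h (78.1% to 4.41%) and ZNF627 1.13 h (94.7% to 7.81%). The longest called half-lives were those of UBQLN1, a ubiquilin, at 13.1 h (96.4% to 32.4%), GSPT1, the release factor eRF3a, at 12.4 h (93.4% to 31.1%), ABHD2 at 12.0 h (74.5% to 34.9%), LMAN1, a cargo receptor, at 11.9 h (91.8% to 37.4%) and WBP11 at 11.8 h (94.8% to 30.2%). These 5 shares fell while total reads of the same genes rose (UBQLN1 by a log2 of 1.12, GSPT1 by 1.10, WBP11 by 1.21, LMAN1 by 0.89 and ABHD2 by 0.62), so the half-lives describe labelled reads against all reads of the library, not the labelled share.

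Each of these 5 calls was fragile. WBP11 was lost without control 0 h replicate 3 (adjusted p = 0.0971) or 6 h replicate 3 (0.0743), LMAN1 without control 0 h replicate 1 (0.0515) or 2 (0.0799) or 6 h replicate 1 (0.0797) or 3 (0.0882), and UBQLN1 without control 0 h replicate 3 (0.0771). ABHD2 was lost without control 6 h replicate 1, 2 or 3 (0.0570, 0.0649 and 0.0581), and GSPT1 likewise (0.0788, 0.0847 and 0.148). With TMM computed on labelled reads the slopes of WBP11, LMAN1, ABHD2, GSPT1 and UBQLN1 were above 0 and past the test (0.164, 0.164, 0.164, 0.166 and 0.169 log2 per h). With no filter all 5 were lost (adjusted p from 0.0505 to 0.0761), as they were from 0, 2 and 4 h alone (0.189 or more).

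**Figure D4:**
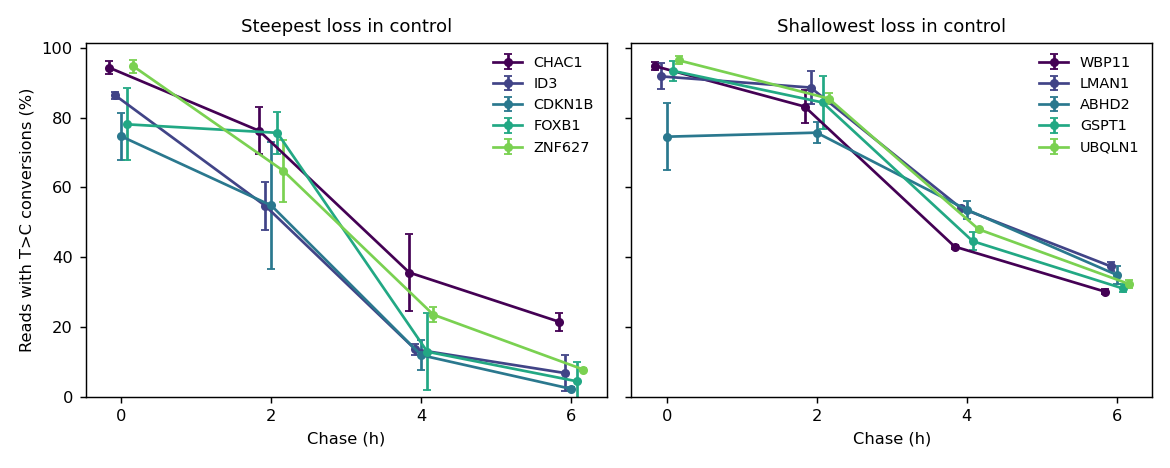
Labelled share of reads (%) against hours of chase in control for the 5 genes with the steepest and the 5 with the shallowest called loss, with points and bars for the mean ± SD of 3 libraries. By 6 h the steepest lay between 2.26% and 21.5%, and the shallowest between 30.2% and 37.4%.

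Across 8763 tested genes labelled reads fell for 6617 in control and rose for 164, and in ZC3H7B-OE they fell for 6340 and rose for 173. The median slope was -0.26 log2 per h in control and -0.24 in ZC3H7B-OE. TMM on labelled reads instead of all reads moved these medians to -0.02 and -0.01 and the split to 1643 falling and 1463 rising in control, and 1120 and 1367 in ZC3H7B-OE. Half-lives were summarised only over the 6617 and 6340 genes whose fall was called, which leaves out genes with rising slopes or uncalled falls. Among these called genes the median was 3.27 h in control (quartiles 2.59 and 4.23), with 531 under 2 h and 430 over 6 h. In ZC3H7B-OE it was 3.50 h (quartiles 2.84 and 4.41), with 332 under 2 h and 432 over 6 h. Of 5879 genes with a called fall in both lines, 3602 had the longer half-life in ZC3H7B-OE. The slopes of the lines correlated across all tested genes with a Spearman rho of 0.743.

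By list, loss in control was faster than that of other genes for mitochondrial ribosomal proteins (61 of 61 fell, median slope -0.40, camera adjusted p = 7.97e-10), the integrated stress response (24 of 25, -0.33, 4.48e-06), glycolytic and housekeeping mRNAs (22 of 22, -0.28, 1.4e-06), immediate early mRNAs (29 of 35, -0.36, 0.00133), the respiratory chain (64 of 65, -0.36, 0.0389) and ribosome biogenesis (23 of 25, -0.35, 0.0471). Each count was the same adjusted over the list alone. Decapping and quality control mRNAs were lost more slowly (10 of 23 fell and 2 rose; 9 and 2 adjusted over the list alone; -0.11, 0.0124). With an estimated correlation all 7 calls were lost (adjusted p = 0.401, 0.311, 0.401, 0.401, 0.821, 0.821 and 0.821). The other 18 lists had camera adjusted p of 0.0807 or more, and fry called 25 of 25. These slopes are relative to all reads of a library, so changes of a gene's total reads enter them. From 0 to 6 h the median log2 change of total reads was -1.30 for mitochondrial ribosomal proteins, -0.43 for the integrated stress response, -1.47 for glycolytic and housekeeping mRNAs, -1.60 for the respiratory chain, -0.23 for ribosome biogenesis and 1.71 for decapping and quality control. It was 1.21 for immediate early mRNAs, which lost label faster although their total reads rose.

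No single gene passed the test of a difference between the lines in the rate of label loss. The edgeR test called 0 of 8763 genes, with 481 at an unadjusted p under 0.05, 419 of them slower and 62 faster in ZC3H7B-OE, and a lowest adjusted p of 0.137; DESeq2 called 1 and limma 0. It called 1 without control 0 h replicate 1, 2 or 3, control 4 h replicate 2 or ZC3H7B-OE 2 h replicate 1, and 63 from the 2, 4 and 6 h libraries alone. In simulated data this test recovered 8.25% of differences of 0.2 log2 per h. MRPS12, a mitochondrial ribosomal protein, had half-lives of 1.40 h in control and 2.06 h in ZC3H7B-OE, RPL29 of the cytosolic ribosome 3.17 and 5.74 h, the enolase ENO1 3.53 and 5.88 h and GAPDH 4.24 and 10.03 h, none past the test. GAPDH has 59 processed pseudogenes, with which its reads may be shared. From 0 to 6 h the labelled share of GAPDH went from 43.4% to 39.1% in control and from 39.2% to 38.1% in ZC3H7B-OE. That of ENO1 went from 59.7% to 52.0% and from 53.7% to 48.3%. Their half-lives thus describe labelled reads against all reads of the library, which changes of total reads enter, not the labelled share. Differences in slope for decay genes were likewise not called: CNOT1 -0.11, PARN -0.16, NEMF -0.26, DIS3L -0.29, AGO4 -0.21, EXOSC7 0.26 and TTC37 0.18 log2 per h (adjusted p of 0.811 or more for every named gene). With single libraries left out TTC37 ran from 0.1001 to 0.268, EXOSC7 from 0.162 to 0.344 and NEMF from -0.315 to -0.174. Without control 0 h replicate 3 the difference fell from 0.141 to 0.0406 for RPL29, from 0.230 to 0.156 for MRPS12, from 0.113 to 0.0783 for ENO1 and from 0.136 to 0.0906 for GAPDH.

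As lists, 4 had slopes shifted toward slower loss in ZC3H7B-OE at the preset correlation. Cytosolic ribosomal proteins (69 tested) had a median difference of 0.11 log2 per h (camera adjusted p = 4.18e-05), mitochondrial ribosomal proteins (61) 0.10 (6.8e-08), the respiratory chain (65) 0.10 (4.18e-05) and glycolytic and housekeeping mRNAs (22) 0.06 (0.00346). Of their members 0 passed over all genes, and adjusted over the list alone 3 of the respiratory chain did. With an estimated correlation each had adjusted p = 0.904. Without control 0 h replicate 3 none of the 4 passed (0.920 and 0.984 with the opposite direction for cytosolic ribosomal proteins and the respiratory chain, 0.146 and 0.623 for the others). With the offset of each gene's own total none passed either, and cytosolic ribosomal proteins and the respiratory chain again had the opposite direction (0.241 and 0.520). From the 2, 4 and 6 h libraries alone cytosolic ribosomal proteins passed in the opposite direction, toward faster loss in ZC3H7B-OE (adjusted p = 0.0143). The other 21 lists had camera adjusted p of 0.0740 or more and 0 members called. Of 100 splits of the libraries between the lines 41 passed as many lists, but a mixed split carries part of the level difference into the slopes.

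Labelled reads at the end of the pulse differed between the lines for 2555 genes, 809 higher and 1746 lower in ZC3H7B-OE. With each gene's own total as offset, 27 differed, 3 higher and 24 lower. Labelled against unlabelled reads of the same gene, compared after the results above were seen, differed for 2 genes at 0 h (0 higher, 2 lower), 170 at 2 h (3 and 167), 69 at 4 h (5 and 64) and 344 at 6 h (233 and 111; 790 and 1026 with the own-total offset). The median log2 odds ratio over all 8763 genes was -0.17, -0.29, -0.15 and -0.02 at 0, 2, 4 and 6 h. The fit does not remove such a shift of all genes, so it enters the lower calls at 2 h and 4 h. From the 6 libraries of a time alone, 0 genes differed at 0 h and 0 at 2 h, so every call at 0 h and 2 h was lost, against 89 at 4 h and 365 at 6 h. At 6 h MRPS12 and MRPL52 of the mitochondrial ribosome had a higher labelled share in ZC3H7B-OE (log2 odds 1.10, adjusted p = 0.00538, and 0.80, 0.0481), and the p53 target CCNG1 a lower one (-1.10, 0.0318). None of 25 lists passed camera at 6 h (lowest adjusted p = 0.0768, for the integrated stress response). Fry called mitochondrial ribosomal proteins and the integrated stress response higher and heat shock genes lower (adjusted p = 0.00719 each).

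These counts of labelled against unlabelled reads moved with single libraries. At 0 h they were 0 without control replicate 1 or 3 or ZC3H7B-OE replicate 1 or 3, 5 without control replicate 2 and 1 without ZC3H7B-OE replicate 2. At 2 h they were 52, 45 and 445 without control replicates 1, 2 and 3, and 101 and 39 without ZC3H7B-OE replicates 2 and 3. At 4 h they were 16, 20 and 16 without control replicates 1, 2 and 3, and 28, 20 and 8 without those of ZC3H7B-OE. At 6 h they were 84, 141 and 95 without those of control, and 142, 95 and 105 without those of ZC3H7B-OE.

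Genes rich in codons ending in A or U tended to be lower in ZC3H7B-OE, and genes rich in codons ending in G or C higher. Across 9417 genes, GC3, the share of codons ending in G or C, correlated with the log2 fold change with a Spearman rho of 0.503 (0.454 without control 0 h replicate 3; 0.329 with no filter and 0.565 with the stricter one; 0.517, 0.271, 0.418 and 0.370 at 0, 2, 4 and 6 h). In the fifth of genes with the lowest GC3 (41.7% or less) the median was -0.42, and 66 genes were called higher and 1021 lower. In the fifth with the highest GC3 (76.1% or more) it was 0.28, with 735 higher and 154 lower. Camera gave adjusted p = 5.17e-18 and 1.26e-11, and p = 0.0120 and 0.0181 with an estimated correlation. The frequency of 29 of 30 codons ending in A or U correlated negatively with the fold change, AUU for isoleucine most (rho -0.440), and that of 29 of 31 ending in G or C positively, CCC for proline most (rho 0.421). Given the U content and length of the 3' UTR and the GC content of the transcript, the partial rho of GC3 was -0.0561, and with the GC content of the 3' UTR in place of the transcript's it was 0.150. The U content of the 3' UTR itself correlated with the fold change with a rho of -0.515, and of -0.272 given GC3. Codons and UTR composition were thus not separated.

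**Figure D5:**
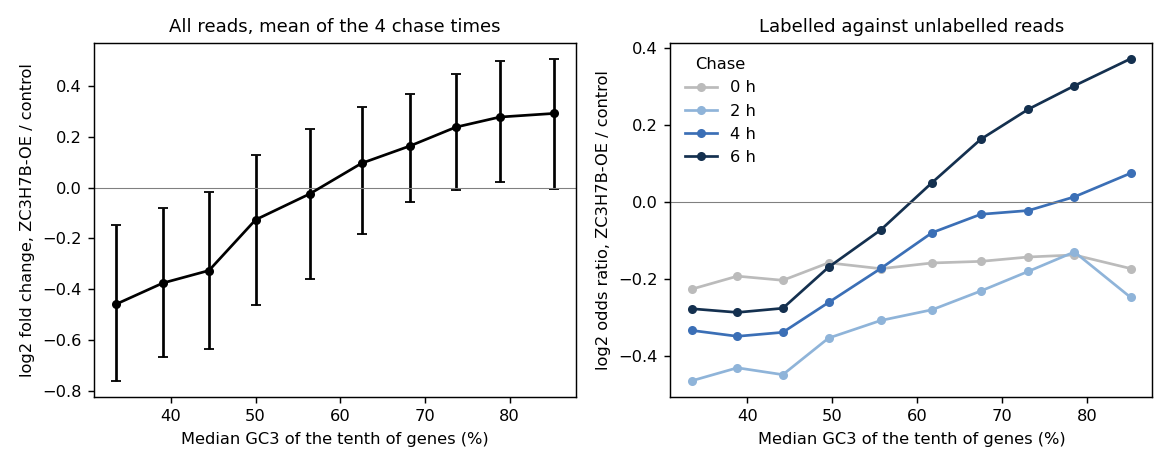
Median log2 fold change of all reads (left; bars from the 25th to the 75th percentile of genes) and median log2 odds ratio of labelled against unlabelled reads at each chase time (right), ZC3H7B-OE against control, for groups of genes of equal size ordered by GC3 (%). The left panel runs from -0.46 in the group with the lowest GC3 to 0.29 in that with the highest.

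The relation of GC3 to the difference in loss rate turned with the fit. GC3 and the slope difference correlated across 8260 genes with a Spearman rho of 0.0219, ranging from -0.0523 to 0.196 with single libraries left out, and the genes of lowest and highest GC3 both had camera adjusted p = 0.916. With each gene's own total as offset rho was 0.401, in a fit of labelled against unlabelled reads 0.220, and with the 2, 4 and 6 h libraries alone 0.356. From 0, 2 and 4 h it was -0.135 and from 0 and 6 h -0.101. Single codons in the main fit had weak correlations, from -0.0963 (AGC for serine, adjusted p = 1.12e-16) to 0.0582 (AUG, adjusted p = 1.44e-06). At adjusted p under 0.05, 16 of 30 ending in A or U were negative and 8 of 31 ending in G or C positive. Codons also went the other way at this threshold. Beside AGC, those ending in G or C with a negative rho included CAC (-0.0489), UCC (-0.0458) and CAG (-0.0405), and GCU was positive (0.0438). The main fit thus gave no clear tilt of codons ending in G or C. Labelled against unlabelled reads correlated with GC3 with rho 0.0221, 0.133, 0.288 and 0.377 at 0, 2, 4 and 6 h. Given the U content and length of the 3' UTR and the GC content of the transcript or of the UTR, the partial rho was 0.0139 or 0.148 at 6 h. It was 0.0322 or 0.172 for the slope difference with the own-total offset. At 6 h the genes of lowest and highest GC3 had medians of -0.28 and 0.33 (camera adjusted p = 1.16e-09 and 7.7e-10; p = 0.00696 and 0.000479 with an estimated correlation). Across genes, the change in level and the slope difference had a Spearman rho of -0.0276 (Pearson -0.0386, 8758 genes), and the change in level and labelled against unlabelled reads at 6 h a rho of 0.326 (Pearson 0.253).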

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

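The values below without single libraries were added after the results were seen, while the test of the change along the chase was planned. The difference between the lines in all reads changed along the chase for 174 of 10038 genes by edgeR's F test of the interaction, with 1846 at an unadjusted p under 0.05, against 748 by DESeq2's likelihood ratio test and 942 with no filter. The count ran from 48 without ZC3H7B-OE 0 h replicate 3 to 910 without control 0 h replicate 1. Of 100 splits of the libraries between lines within each time, the real one included, 4 called as many genes, and the highest other split called 1165. These splits cannot decide on chance here, because a mixed split carries part of the level difference between the lines into the interaction. What sets the split with 1165 apart was not tested.

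Of the genes named by the fixed rule, 5 were picked out because their own line difference changed along the chase. LMAN1, a cargo receptor of the secretory pathway, had log2 differences between ZC3H7B-OE and control of -1.31, -1.34, -0.42 and -0.46 at 0, 2, 4 and 6 h (adjusted p = 0.00834). UBQLN1, a ubiquilin, had -1.24, -0.47, -0.15 and -0.04 (adjusted p = 0.00238), and the deadenylase CNOT7 -1.34, -0.04, -0.19 and -0.19 (adjusted p = 0.00454). DDIT4, an inhibitor of mTORC1, had -0.57, -0.52, -1.24 and -1.24 (adjusted p = 0.0388). ENO1, a glycolytic enolase, had -0.13, -0.09, 0.61 and 0.35 (adjusted p = 0.0313).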

How the results depend on the processing

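Chosen after the results were seen were the 2, 4 and 6 h set, all tests of labelled against unlabelled reads, 6 h against 0 h in ZC3H7B-OE, 2 h against 0 h in control, single libraries left out for the separate times, the chase, the lists, the correlations and the labelled share, and filters for these. Also chosen then, for the lists and the correlations, were times left out, other sets of times and the own-total offset. GC3 and the loss rate with that offset was planned. The cause of a change was not tested except where fewer genes or libraries enter by construction. DESeq2's Wald test kept the direction and the call of 107 of 107 named values, ZC3H7B removed 52 of 52, the stricter filter 62 of 62, DESeq2 size factors 104 of 105, no filter 102 of 107 and limma 85 of 87. With 0, 2, 4 or 6 h left out of the mean, 45, 51, 49 and 48 of 53 were kept. From 0, 2 and 4 h 35 of 41 were kept, from 2, 4 and 6 h 33 of 41 and from 0 and 6 h 32 of 33. With the own-total offset 37 of 44 were kept, with TMM on labelled reads 39 of 44, and for labelled against unlabelled reads 31 of 34. With each library left out, 2213 of 2264 named values kept both, 40 lost the call, 3 gained it and 8 reversed. At the real depth, 8.25% of simulated differences of 0.2 log2 per h in the loss rate were recovered; other depths were not simulated, so what sets this limit was not tested.

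Between the lines in all reads, 1983 of 4594 genes passed with a minimum of 1.5-fold. From the 6 libraries of a time alone, 791 passed at 0 h (117 higher, 674 lower), 3104 at 4 h (1452 and 1652) and 3286 at 6 h (1599 and 1687), and 589 (439 and 150) for 2 h against 0 h in control. With single libraries left out, counts ran from 575 to 847 at 2 h, 1038 to 1567 at 4 h and 890 to 1239 at 6 h. The change along the chase gave 942 genes with no filter, 748 by DESeq2's likelihood ratio test and 48 to 910 with single libraries left out. An estimated correlation left 2 lists in all reads and fry called 17.

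Slopes of labelled reads within a line were counted here whether falling or rising. They were called for 3571 genes in control and 3498 in ZC3H7B-OE with the stricter filter, which tests fewer genes. With TMM on labelled reads the counts were 3106 and 2487, and they were 4267 and 4225 from 0, 2 and 4 h. The difference in loss rate gave 1 gene by DESeq2, 2 with TMM on labelled reads, 63 from 2, 4 and 6 h, 1 from 0 and 6 h, 32 for labelled against unlabelled reads at 0 and 6 h, and 0 to 1 with single libraries left out. Lists in the loss rate numbered 0 with an estimated correlation, fry or the own-total offset, 1 from 2, 4 and 6 h, and 0 to 5 with single libraries left out. Labelled reads at 0 h gave 27 genes with the own-total offset.

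Labelled against unlabelled reads gave 0 genes from the 6 libraries alone at 0 h and 2 h. With the own-total offset, which makes more false calls in simulated data, they gave 27, 39, 1078 and 1816 genes at 0, 2, 4 and 6 h. With single libraries left out they gave 0 to 5, 39 to 445, 8 to 28 and 84 to 142.

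GC3 and all reads had a rho of 0.329 with no filter, 0.565 with the stricter filter, 0.421 with 0 h left out, 0.437 and 0.572 among genes of lower and higher expression, and 0.454 to 0.505 with single libraries left out. GC3 and the loss rate had 0.401 with the own-total offset, 0.356 from 2, 4 and 6 h, -0.135 from 0, 2 and 4 h, -0.101 from 0 and 6 h, 0.220 for labelled against unlabelled reads, and -0.0523 to 0.196 with single libraries left out. GC3 and labelled against unlabelled reads at 6 h had 0.350 to 0.365 so. Level and loss rate had 0.329 with the own-total offset and -0.129 to 0.164 with single libraries left out.

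Reversed slope differences, none called, were, with the own-total offset, ZC3H7A -0.0501, BTG2 0.0786, CNOT7 -0.0254, NDUFA5 -0.0317, LSM1 -0.00382, GIGYF1 0.0133 and TNRC6B 0.0692. From 2, 4 and 6 h they were ZC3H7A -0.126, CNOT7 -0.0467, TARBP2 -0.0019, NDUFA4 -0.0369, LSM1 -0.0903, TTC37 -0.0197 and AGO1 0.0524. For labelled against unlabelled reads they were BTG2 0.158, GIGYF1 0.00987 and TNRC6B 0.0188, from 0, 2 and 4 h ZNF598 -0.0414, and from 0 and 6 h ZC3H7A -0.0155. Single libraries left out gave -0.0612 to 0.0566 for ZC3H7A and -0.00739 to 0.125 for LSM1. TMM on labelled reads reversed the slopes in control of WBP11, LMAN1 and ABHD2 (0.164 each), GSPT1 (0.166) and UBQLN1 (0.169).

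The lists of cytosolic ribosomal proteins and the nuclear-encoded respiratory chain reversed with the own-total offset (adjusted p = 0.241 and 0.520) and from 2, 4 and 6 h (0.0143, which passes, and 0.474), as mitochondrial ribosomal proteins did from 2, 4 and 6 h (0.565). With single libraries left out, adjusted p ran from 5.05e-08 to 0.920 for cytosolic ribosomal proteins and from 2.73e-07 to 0.984 for the nuclear-encoded respiratory chain.

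Replicate numbers did not pair the libraries: deviations of same-numbered libraries correlated by -0.00476 on average over 84 pairs (-0.164 to 0.214), and 10 of 24 libraries correlated best with their own number. The replicate block gave 4533 genes between the lines, 135 for the change along the chase and 1 for labelled against unlabelled reads at 0 h, and ended the call of EXOSC8 (adjusted p = 0.0661) among 107 named values.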

Other observations

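Of the tests in this part, those of 3' UTR composition, of GC3 without control 0 h replicate 3, of the correlation between the lines, of lists along the chase, of labelled against unlabelled reads, and of 6 h against 0 h in ZC3H7B-OE and 2 h against 0 h in control were chosen after the results were seen. Genes of low GC3 more often rose than fell along the chase in both lines. In control, of the 1884 genes with the lowest GC3, 1071 were higher at 6 h than at 0 h and 230 lower (median log2 1.01), against 216 and 796 of the 1884 with the highest (median -0.59). In ZC3H7B-OE the counts were 1247 and 112 (median 1.48) against 157 and 989 (median -0.80). Spearman's rho of GC3 with the change was -0.391 in control and -0.531 in ZC3H7B-OE, and that of the U content of the 3' UTR 0.434 and 0.563. Given the U content and length of the UTR and the GC content of the transcript, the partial rho of GC3 was -0.115 and -0.105, and with the GC content of the UTR instead -0.108 and -0.181, so codons and UTR composition were not separated. The slope of labelled reads in control was also steeper at high GC3 (rho of GC3 with the slope -0.315) and shallower at high U content (rho 0.344). This slope is relative to all reads of a library, so the changes of total reads enter it. The labelled share went the other way by U content. Its median in control fell from 92.4% to 26.6% over 6 h in the fifth of genes with the most U. In the fifth with the least U it fell from 79.5% to 37.7%.

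Genes of low GC3 were lower in ZC3H7B-OE, with a rho of 0.503 between GC3 and the fold change. A loss of U-rich reads that depends on the label would leave unlabelled reads without this relation, if these came from RNA without s4U. In unlabelled reads at 6 h rho was 0.256 (SD over the replicate numbers 0.0179). That argues against such a loss as the whole cause, unless many unlabelled reads came from labelled RNA. Given the UTR's U content and length and the GC content of the transcript or of the UTR, the partial rho in these reads was -0.0674 or 0.0268. Without control 0 h replicate 3 rho was 0.454, which argues against that library as the cause. Base composition of the 3' UTR stays open as a candidate explanation, since the partial rho was 0.150 (SD 0.0105) given the UTR's U content, GC content and length, and -0.0561 (SD 0.0317) given the GC content of the whole transcript in place of the UTR's. An effect of ZC3H7B through codons and a difference between the lines from before induction also stay open, as no uninduced libraries were analysed here.

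All reads of a gene often changed between 0 and 6 h of chase, which a return of U-rich labelled reads after the chase could produce. By 2 h the rho of U content of the 3' UTR with the change was 0.490 in ZC3H7B-OE (SD 0.0790) and 0.131 in control (SD 0.214). This was planned to exclude the explanation, because the labelled share of all reads barely fell by 2 h. It leaves the explanation open, because in the genes richest in U the median share fell by 11.8 percentage points in control and 14.9 in ZC3H7B-OE by then. A single atypical control library is argued against by the rho of 0.874 across genes between the changes in the lines, and an effect of the medium or of uridine on the cells was not tested.

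Labelled shares of some abundant mRNAs fell little in control from 0 to 6 h: GAPDH, with 59 processed pseudogenes, went from 43.4% to 39.1%, EEF1A1, with 37, from 50.4% to 50.2%, and ENO1, with 2, from 59.7% to 52.0%, while ACTB, with 9, went from 83.3% to 43.8%, PPIA, with 86 and only 3.55 CPM at 0 h, from 100% to 7.80%, and MYC, with 0, from 89.8% to 6.03%. Reads shared with processed pseudogenes may contribute, since mismatches to a copy can read as conversions at all times: the fall was 19.7 percentage points smaller in 172 genes with at least 5 processed pseudogenes than in 8312 others of like expression. Few uridines in the 3' UTR may contribute as well, as their number correlated with the fall with a rho of 0.327. Neither accounts for every mRNA: ENO1 fell little with 2 pseudogenes, EEF1A1 fell little with 652 UTR uridines, and the shares of PPIA and ACTB fell. The genes with pseudogenes also had fewer UTR uridines (medians 207.5 and 349), so these explanations overlap, and a slow turnover of these mRNAs was not tested apart from them.

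Results of fits across all genes were set against other splits of the same libraries, each with 100 splits, the real one included: lines reassigned within each time, or, for the loss within a line, times reassigned within it. Chance is argued against for the 4594 genes that differed between the lines (1 split as large, highest other 1040) and for GC3 and all reads (rho 0.503, 3 splits, 0.519). It is also argued against for slopes of labelled reads, falling or rising, in control (6781 genes, 1 split, 466) and in ZC3H7B-OE (6513, 1 split, 0). Chance is not excluded for the 4 lists in all reads (42 splits, 8). For differences between the lines over time the splits cannot decide, so chance stays open. A mixed split carries part of the level difference between the lines into the slopes and the interaction. This holds for the 174 genes whose difference changed along the chase (4 splits, 1165). It holds for the 481 genes at an unadjusted p under 0.05 in the loss rate (17 splits, 1980) and the 4 lists in the loss rate (41 splits, 10). It also holds for GC3 and the loss rate (rho 0.0219, 98 splits, -0.562) and for level and loss rate (rho -0.0276, 98 splits, -0.734).

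With 3 against 3 libraries 10 splits exist, too few for a share under 0.05. The real count and the highest other were 3132 and 1 at 0 h, 949 and 19 at 2 h, 1772 and 0 at 4 h and 1583 and 0 at 6 h between the lines. For 6 h against 0 h they were 6085 and 0 in control and 6369 and 0 in ZC3H7B-OE, for 2 h against 0 h in control 2447 and 1, and for the lists along the chase 9 and 10, with 4 of the 10 splits passing at least 9. For labelled reads at 0 h they were 2555 and 0, and for labelled against unlabelled reads 2 and 0 at 0 h, 170 and 0 at 2 h, 69 and 1 at 4 h and 344 and 0 at 6 h. For GC3 and labelled against unlabelled reads at 6 h rho was 0.377 and the highest other 0.2.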
